A study of Mus musculus with 5 samples.

How the data were processed

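Total RNA of mouse cerebral cortex at stage E17.5 was isolated with Trizol and sequenced on an Illumina instrument as paired reads of 150 bases, per the labels' protocols. The authors deposited 1 table of whole-number counts per gene for the 5 libraries, 3 of Satb2 knockout and 2 of wild-type cortex. The submitters' processing notes name Trim Galore (a read trimmer), STAR 2.6 (an aligner), Salmon 1.5 (a quantifier of transcripts) and the genome build GRCm39. How these were combined, which annotation was used, whether strand was used and how the whole-number counts were obtained are not given in the sources used here. Salmon gives estimated counts that need not be whole, so the deposited counts may have been rounded. This cannot be told from the values, and it changes a gene's count by less than 1. No gene had 0 counts in all 5 libraries, so genes without any count had been left out before. The table had 6 genes whose 5 counts repeated those of another gene exactly with a total over 20. Such copies, and genes that share reads with a near-identical copy, cannot be named here.

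The table has no column of gene names or identifiers. Row order was not used to assign names, and the reference annotation at hand was of another build, so no genome position was used. The tests of 27 gene lists planned before the data were examined were not run for this reason. The depth of a library was its column total, and the totals range from 15849714 to 21896526 counts. Total depth sets the value of 1 count at 0.0457 to 0.0631 CPM before TMM scaling. Gene CPM values and the limits for genes at 0, set at 3 counts over the group, include the TMM factors.

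Genotype was taken from the labels of each sample. The column named S52.2 carries the group WT in its name, but no sample title has that number (the WT titles have S2 and S2.2), so it was used as a WT library without assignment to a sample and is called WT 2. Numbers of the KO libraries follow accession order and pair no samples. The 2 sets of libraries were read from the column names: those with a number that begins with 52 (KO 2, KO 3 and WT 2) and the others (KO 1 and WT 1). What the numbers stand for is not given in the sources used here, and no label gives a litter, sex, library batch or date.

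Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by genotype, which left 16148 genes, and scaled with TMM factors, which lay between 0.940 and 1.04. Dispersions were estimated with estimateDisp, and KO was tested against WT with glmQLFit and glmQLFTest. An adjusted p under 0.05 (Benjamini-Hochberg) was the threshold, with no minimum fold change. The model with genotype alone was fixed before the data were examined, as were the rule for named genes and most alternatives. The model with set and genotype, the test between the sets and the test of their interaction were added after the set difference had been seen. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Principal components and correlations used log2 CPM with a prior count of 2, and so did the comparison of ratios between the sets, while the ratios of single genes and those in the plot of both sets used a prior count of 0.5.

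The rule named the 10 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 2 CPM and no overlap between KO and WT libraries. The model with genotype alone passed no gene, so the rule was applied to the model with the set. Because the genes have no names, only the first 2 in each direction were given. The parts of the rule that depend on gene symbols could not be applied.

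Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a filter of 1 CPM in 2 samples, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Thinning all libraries to the smallest total, leaving out the 100 most abundant genes and fitting set S52 alone were added later. The edgeR fits were tested on simulated counts for the same 16148 genes, in which 200 genes were changed. With the set difference kept and the set in the model, 83 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were called, and 5.18% of the calls were false. When each gene's own estimated dispersion was used in the simulation in place of the trend, 11.8% of the calls were false, above the 5% aimed at. The 99 calls of that model may hold a like excess. Their own false share is not known, because the simulation fixed the number and size of the changes.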

Results

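RNA sequencing was used to compare the cerebral cortex of Satb2 knockout mice with that of wild-type mice at stage E17.5, late in gestation. Satb2 encodes a DNA-binding protein of the nucleus that is expressed in developing projection neurons of the cortex. The knockout line was made with CRISPR-Cas9, and the mice were of the C57BL/6J strain. The design had 1 factor, genotype, with 3 knockout (KO) libraries and 2 wild-type (WT) libraries. Nothing in the labels says whether the libraries came from separate embryos, so the p-values measure only the spread between these libraries. The count table held 20994 genes and 5 columns of counts, without gene names or identifiers. Genes are therefore given by their row number in the table, no chromosome position or annotation can be attached to them, and the Satb2 transcript itself could not be checked in any library. The 27 marker and pathway lists fixed before the data were examined could not be applied.

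KO 1, KO 2 and KO 3 had totals of 21896526, 21205607 and 20069743 counts, and WT 1 and WT 2 had totals of 19567332 and 15849714. By these totals, 1 count was worth 0.0457 CPM (the usual scaling of counts to a common library total) in the deepest library and 0.0631 CPM in the shallowest. The CPM values of genes given below were also scaled by the TMM factors, so 1 count differs slightly from these values there. Between 19490 and 20109 genes had at least 1 count in a library. The 10 most abundant genes took between 5.88% and 6.77% of a library's counts. After a filter on low counts, 16148 genes were tested, and they held 99.9% of all counts.

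The libraries differed far more by a grouping in their names than by genotype. The column names carry the numbers S52.4, S52.5 and S52.2 for KO 2, KO 3 and WT 2, called here set S52, and S1 and S2 for KO 1 and WT 1, called here set S1/S2. The first principal component of log2 CPM held 63.9% of the variance and placed the libraries of set S1/S2 at -51.4 and -58.5 and those of set S52 at 42.0, 36.6 and 31.3. Pearson correlations of log2 CPM across genes were between 0.982 and 0.986 for the 4 pairs of libraries within a set (KO 1 with WT 1, and KO 2, KO 3 and WT 2 with each other). Between the sets they were between 0.949 and 0.958, and the 2 WT libraries correlated at 0.958. The second component, with 15.7% of the variance, placed the 3 KO libraries at 25.8, 19.8 and 6.24 and the 2 WT libraries at -21.0 and -30.9. As a check for a library entered in duplicate, the counts of each pair were compared, and the closest pair, KO 2 and KO 3, had a chi-square of 9.60 per degree of freedom over 17300 genes. All 5 libraries were therefore counted separately.

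**Figure D1:**
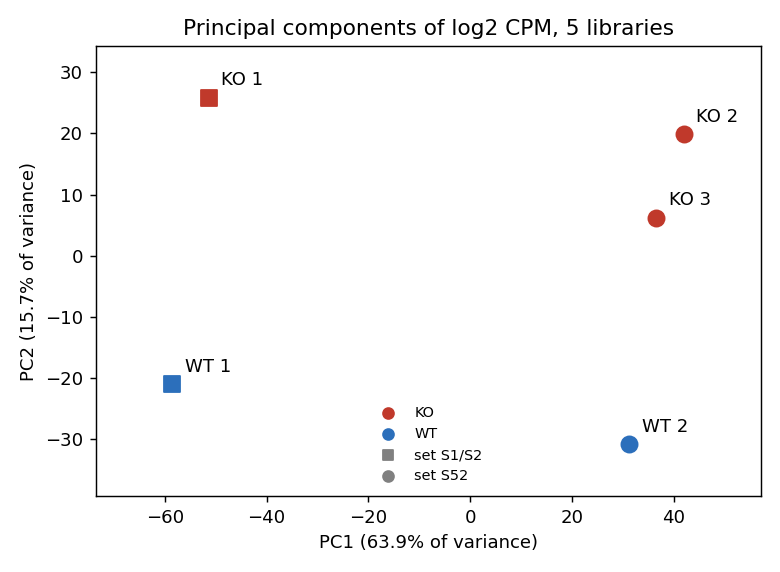
Scores of the 5 libraries on the first and second principal components of log2 CPM over 16148 genes. Color gives the genotype and shape the set, and each axis gives its percent of the variance. The sets lie apart on the first axis, with set S1/S2 at -51.4 and -58.5, and the genotypes lie apart on the second, with KO at 6.24 or more and WT at -21.0 or less.

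With genotype and set both in the model, 5940 genes differed between the sets at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), which was 36.8% of the genes tested. Of these, 2886 were higher and 3054 lower in set S52. The difference was at least 1 on the log2 scale for 1469 of them, 782 higher and 687 lower. Counts of 0 marked some of the differences: 6 genes had no count in either library of set S1/S2 and at least 2 CPM in each library of set S52, the most abundant at a mean of 57.7 CPM. The opposite held for 3 genes, of which the most abundant had a mean of 8.85 CPM in set S1/S2. These counts of genes at 0 were made after the values were seen. Without KO 1 the number of genes that differed between the sets was 3048.

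The comparison of KO with WT cortex asks which transcripts change when Satb2 is absent. Fitted on all 5 libraries with genotype alone, it gave no gene at an adjusted p under 0.05 by edgeR's quasi-likelihood test. The lowest adjusted p was 0.139, and 389 genes had an unadjusted p under 0.05, fewer than 5% of the genes tested. DESeq2 called 47 genes on the same counts, 19 higher and 28 lower in KO, and limma-voom called 0. The biological coefficient of variation was 28.0% in this fit. In simulated counts that kept the set difference, this fit recovered 51 of 100 genes changed by 2 on the log2 scale and 1 of 100 changed by 1.

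Within the sets, KO and WT differed at 99 genes. This fit had the set as an additive term, was added after the set difference had been seen, and called 34 genes higher and 65 lower in KO at an adjusted p under 0.05 (edgeR). The biological coefficient of variation was 10.7%. All 99 genes had the same direction in set S1/S2 alone, in set S52 alone and in the fit without the set, which follows largely from their selection by this fit on the same libraries. In 88 of the 99, 29 higher and 59 lower, every KO library lay on one side of both WT libraries. This too follows largely from the selection. Among all genes tested, 13.7% were separated in this way. The 34 genes that rose had a median log2 fold change of 0.97, and 18 of them had a mean of at least 50 CPM. The 65 genes that fell had a median log2 fold change of -1.06, and 28 of them had a mean of at least 50 CPM. A change of at least 1 on the log2 scale was reached by 14 of the genes that rose and 36 of those that fell. Leaving out KO 2 or KO 3 gave 184 and 164 genes. Leaving out KO 1 or WT 1 gave 235 and 213, and in both cases the genotype difference came from set S52 alone. Leaving out WT 2 gave 114, of which 46 were among the 99. More genes rose than fell without WT 2 (60 and 54) and without KO 3 (84 and 80).

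Among genes with a mean of at least 2 CPM and no overlap between the genotypes, the 2 with the largest increase had no count in either WT library. The gene in row 17370 had 116, 166 and 92 counts in KO 1, KO 2 and KO 3, or 5.82 ± 1.64 CPM (SD, n = 3). Against the limit that 3 counts over the WT group allow, 0.0869 CPM, it was at least 67.0-fold higher in KO (adjusted p = 0.00804 with the set as a block and 0.213 without it, edgeR). The gene in row 19629 had 123, 69 and 67 counts in the KO libraries, or 4.05 ± 1.49 CPM (SD, n = 3), and was at least 46.6-fold higher (adjusted p = 0.00521 with the block and 0.284 without, edgeR). The limits cover counting error only. The rule would have left out sex-linked genes, which could not be done without names, and no label gives the sex. A like pattern of 0 counts separated the sets in 6 and 3 genes. Whether these 2 genes follow genotype or another difference between the libraries was not tested. In the other 32 genes that rose, counts were found in both genotypes and the largest log2 fold change was 2.01.

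Under the same limits on mean CPM and overlap, the 2 genes with the largest decrease kept some expression in KO. Without these limits the largest decrease among the 65 genes was -4.41 on the log2 scale. The gene in row 15448 had 1.04 ± 0.489 CPM in KO (SD, n = 3) and 17.9 ± 4.32 CPM in WT (SD, n = 2). Its log2 fold change was -4.01 with a standard error of 0.31 and an adjusted p of 0.00228 with the set as a block (edgeR), against 0.217 without it. It was -4.02 in set S1/S2 and -4.14 in set S52. The gene in row 11720 had 7.55 ± 1.01 CPM in KO (SD, n = 3) and 55.1 ± 17.1 CPM in WT (SD, n = 2). Its log2 fold change was -2.88 with a standard error of 0.19 and an adjusted p of 0.00121 with the block (edgeR), against 0.139 without it. It was -2.35 in set S1/S2 and -3.24 in set S52. None of the 4 named genes passed the threshold between the sets, where their adjusted p lay between 0.109 and 0.807 (edgeR).

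**Figure D2:**
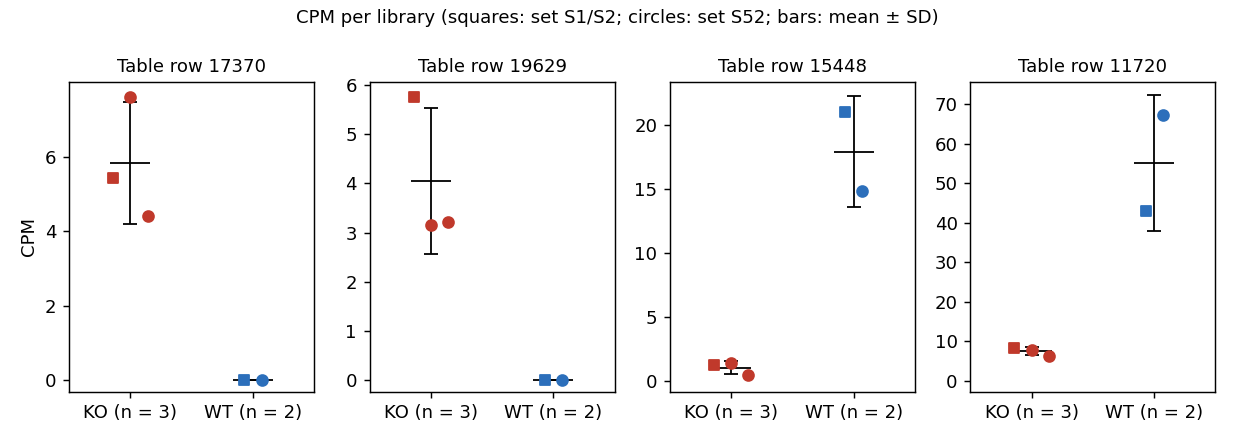
CPM of the 4 named genes in each library, on linear axes that differ between panels. Squares are set S1/S2, circles are set S52, and black bars give the mean and SD of 3 KO and 2 WT libraries. The genes in rows 17370 and 19629 are at 0 in both WT libraries, and those in rows 15448 and 11720 are higher in both WT libraries than in any KO library.

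The sets share no library, so the KO and WT difference in one can be set against that in the other. Over the 13186 genes with a mean of at least 2 CPM, the log2 ratio of KO 1 to WT 1 and that of the mean of KO 2 and KO 3 to WT 2 had a Pearson r of 0.282 and a Spearman rho of 0.223. The difference KO 2 minus KO 3, libraries of the same genotype, had a Pearson r of 0.242 and a Spearman rho of 0.241 with the log2 ratio of KO 1 to WT 1. A correlation of this size was thus not limited to genotype. These correlations are across genes, which are not independent replicates. Over these 13186 genes, 57.9% had the same sign in both sets. Of the 100 genes with the largest ratio in set S52, 81 had the same sign in set S1/S2. Of the 100 with the largest ratio in set S1/S2, 75 had the same sign in set S52. Without a minimum CPM these counts were 70 and 63, and at a mean of at least 10 CPM they were 88 and 82. Of the 100 genes with the largest ratio in set S1/S2 at 2 CPM or more, 62 had the same sign in KO 2 minus KO 3. Of the 100 genes with the largest such difference, 66 had the same sign in set S1/S2. The order of these 2 libraries is arbitrary, and the reverse order would give the opposite signs, whereas KO minus WT has a fixed direction. For the mean of KO 3 and WT 2 minus KO 2, the Pearson r was -0.349, larger in size than for genotype. In that contrast 28 and 30 of 100 genes had the same sign. KO 2 thus tended to differ from KO 3 and WT 2 in the direction in which KO 1 differed from WT 1. This contrast holds part of the genotype difference, because it sets KO 2 against WT 2 as well as KO 3. For the mean of KO 2 and WT 2 minus KO 3, the Pearson r was 0.0352, with 41 and 42 of 100. The contrasts of the 3 libraries of set S52 sum to 0 for each gene, so these values are not independent of those for WT 2. When set S52 was fitted alone, with 1 WT library and all spread taken from KO 2 and KO 3, edgeR called 294 genes, which compares these libraries only. Of the 290 that were also tested over all libraries, 248 had the same sign in set S1/S2. With KO 2 or KO 3 set apart in place of WT 2, the same fit called 0 and 4 such genes, and 3 of the 4 had the same sign. In those other fits the spread came from a KO library and WT 2, so any genotype difference would widen it and fewer calls follow from the design. For WT 2 set apart, the median change was 0.91 on the log2 scale in set S52 and 0.47 in the same direction in set S1/S2.

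**Figure D3:**
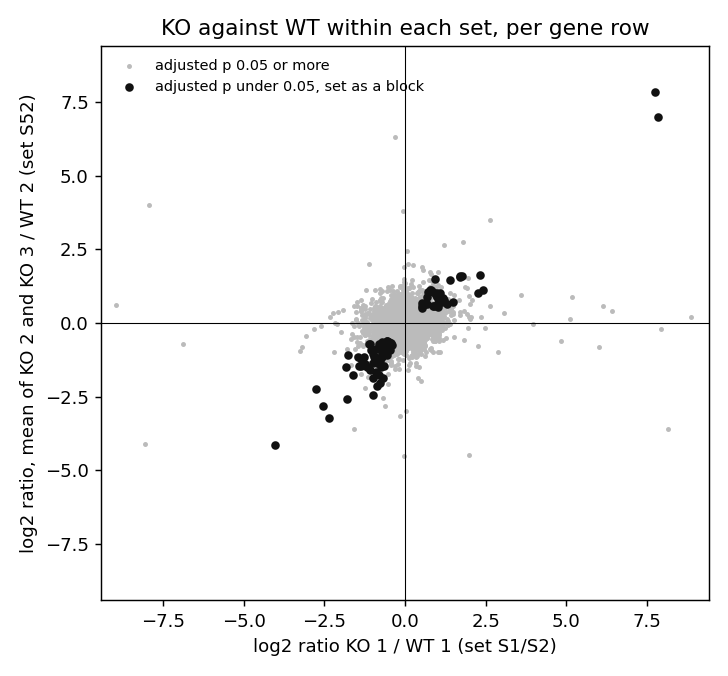
Log2 ratio of KO to WT in set S1/S2 (horizontal axis, 1 library each) and in set S52 (vertical axis, the mean of 2 KO libraries against 1 WT library) for genes with a mean of at least 2 CPM. Black points are genes at an adjusted p under 0.05 with the set as a block, and they lie in the quadrants where both sets have the same sign, largely because that fit selected them on these libraries. Genes with no count in a library lie far from 0 along 1 axis or both.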

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

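The test of whether the KO and WT difference itself differed between the sets was chosen after the set difference had been seen. It found 30 genes at an adjusted p under 0.05 (edgeR, interaction of genotype and set), 13 with a more positive change in set S52 and 17 with a more negative one. They were singled out because the same contrast gave different sizes in 2 sets of libraries. In 16 of the 30 the direction was opposite in the sets, and 4 of the 30 were among the 99 genes called within the sets. Their median absolute log2 ratio was 1.48 in set S1/S2, with 1 library per genotype, and 0.709 in set S52. Across all genes 1097 had an unadjusted p under 0.05, where 807.4 would be reached by chance. This model leaves 1 residual degree of freedom, the difference between KO 2 and KO 3. Setting each library of set S52 apart in turn in place of WT 2 gave at most 4 genes, so 1 of the 3 choices, the real one, gave as many as 30, and 3 choices are too few for a share under 0.05. With KO 2 or KO 3 set apart, the residual is the difference between a KO library and WT 2, so fewer calls follow from the design. No group had the 4 libraries that a test for single outlying libraries needs.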

How the results depend on the processing

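Fitted with genotype alone, KO against WT kept a count of 0 under RLE and upper-quartile factors, limma-voom, both other filters, a fold minimum, thinning, removal of the 100 most abundant genes and the removal of each library. Exceptions were DESeq2, with 47 genes (19 higher, 28 lower), and the set as an additive block, with 99 (34 higher, 65 lower). The thinning, the removal of abundant genes and every fit with the set were chosen after the data had been seen. With the set as a block, DESeq2 gave 256 genes (113 higher, 143 lower), no filter gave 196 (90 and 106), set S52 alone gave 294 (121 and 173), and a log2 fold change of at least 1 left 50 (14 and 36). Thinning gave 147, of which 56 were higher. Leaving out 1 library in turn gave 114 to 235 genes, 60 to 99 higher and 54 to 136 lower. The cause of the larger counts was not tested, except that the fold minimum keeps fewer genes by construction. The counts without WT 2 rest on 1 library per genotype in set S1/S2, those without KO 1 or WT 1 rest on set S52 alone, and the spread then comes from KO 2 and KO 3. The share of higher calls was 34.3% and stayed within 10 percentage points under RLE (34.3%) and upper-quartile factors (37.6%), but it was 45.9% without a filter and 52.6% without WT 2, so that more genes fell than rose does not hold without that library or without KO 3 (51.2%). All 99 genes kept their direction in each refit with the set, except 1 that was among the removed abundant genes. The 4 named genes passed the threshold in all 14 alternatives with the set, of which 3 amount to set S52 alone, with adjusted p of at most 0.0128. With genotype alone, DESeq2 passed all 4 named genes (adjusted p of at most 2.98e-05), whereas RLE and upper-quartile factors, limma-voom and both other filters passed none of them. The count between the sets lay between 3048 and 5693 when 1 library was left out. The correlation of ratios between the sets lay between 0.19 without a minimum CPM and 0.364 at 10 CPM. Of 107 alternative values of these results, 32 moved by more than 1.5 times or away from 0. Depth limits the genes at 0: a true WT level under 0.0869 CPM would give on average fewer than 3 counts over both WT libraries.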

Other observations

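The tests of the column name and of the difference between KO 2 and KO 3 were chosen after the results were seen, and the label search rests on labels read beforehand. The predictions for thinning, abundant genes, agreement in sign and other splits were written before those values were computed.

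The difference between sets S1/S2 and S52 covered 5940 genes. It was not reduced by equal depth, since 98.8% as many genes were called after every library was thinned to the smallest total, nor by removal of the 100 most abundant genes, after which 99.8% as many were called. That WT 2 belongs to set S1/S2 is argued against by its correlations, whose lowest value with the KO libraries of set S52 exceeded its highest value with set S1/S2 by 0.0240, which says nothing about its genotype. Library batch, litter, sex or exact age of the embryos may each underlie the sets and cannot be told apart, because 0 label fields give any of them. A split of the libraries along the sets, with KO 1 and WT 1 against the rest, called 5382 genes without a block, whereas the real genotype split called 0, a count that all 10 splits reach by construction.

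The genotype difference within the sets was a hypothesis found and tested on the same 5 libraries. Lower depth of WT 2 is argued against by thinning, after which the number of calls was 148% of the unthinned one. A difference found in WT 2 alone is argued against only above a minimum abundance. Of 100 genes, 81 had the same sign in set S1/S2 at a mean of at least 2 CPM and 88 at 10 CPM. Without a minimum it was 70, which the prediction left undecided. These sign counts do not tie the difference to genotype. Of the 100 genes with the largest difference between KO 2 and KO 3, 66 also had the same sign in set S1/S2 when taken as KO 2 minus KO 3, an arbitrary order. The mean of KO 3 and WT 2 minus KO 2 gave 28 of 100, with a Pearson r of -0.349 against 0.282 for WT 2. These contrasts are not independent: the former sets KO 2 against WT 2 as well as KO 3. It thus holds part of the genotype difference and cannot decide the question. An axis of variation other than genotype, such as dissection or age, stays open. KO 2 and KO 3 share a genotype, yet the difference KO 2 minus KO 3 had a Pearson r of 0.242 with KO 1 minus WT 1. Of the 100 genes with the largest ratio of KO 1 to WT 1, 62 had the same sign in it, with a median of 0.10 on the log2 scale in that direction, against 75 and 0.42 for the genotype contrast of set S52. The real assignment of 1 WT library per set called 99 genes and the highest of the other 5 called 0, but 1 of 6 assignments cannot give a share under 0.05. Each of the other 5 puts KO and WT libraries under 1 label. Any genotype difference would then widen the spread, so fewer calls follow from the design.

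Of the 99 genes called for genotype, 46 also differed between the sets, where 36.4 would be reached at the rate of all genes tested. This excess was not tested, and that rate is not matched for abundance. The median of the mean CPM was 52.8 for the genes that rose and 44.0 for those that fell, against 21.2 for all genes tested. Genes in which all KO libraries lay on one side of both WT libraries made up 13.7% of the genes tested, 1106 above and 1101 below, where chance gives 20% in libraries without a set difference.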
